A study of Gallus gallus with 3 samples.

How the data were processed

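RNA was measured in 3 libraries of chicken DT40 cells, a B cell line derived from a bursal lymphoma that is widely used for gene targeting. All 3 were of the DT40-ASF line, in which, from general knowledge of the line and not from the deposited files, the chicken SRSF1 gene is disrupted and a human copy (ASF) is supplied. SRSF1 is an SR protein, a splicing regulator, and SRSF1-3 is a splice isoform of it. The groups were taken from the genotype label: 1 untransfected control library and 2 libraries of cells with an SRSF1-3 knock-in, named clone 41 (knock-in replicate 1) and clone 47 (knock-in replicate 2). Nothing in the labels says how cultures were replicated within a clone, so the clones were the only replicates. The p-values of single genes for knock-in against control measure only the spread between these 2 libraries.

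Per the labels' protocols, mRNA was enriched from total RNA, libraries were made with a strand-specific kit and amplified by PCR, and they were sequenced as paired ends. Per the submitters' processing notes, TopHat2, TopHat, Bowtie, Cufflinks 2.2.1 and Cuffdiff were used with the chicken genome build galGal4. The deposited read counts are whole numbers per gene, which the authors' cover sheet calls absolute read counts; the tool that counted the reads, the annotation release and the strand setting are not given in the sources used here. The deposited FPKM values (fragments scaled by transcript length and library size) are what the authors' cover sheet calls normalised read counts, and any further library scaling by the authors is not given in the sources used here. The table of counts listed 11877 genes and that of FPKM 11929, of which 11546 were in both. Genes are named as the files name them. Counting at gene level does not separate SRSF1 isoforms, and reads of near-identical copies, such as the H3.3 genes H3F3B and H3F3C, may have been split between them.

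The total count was 44868987 for the control, 42439517 for clone 41 and 41760372 for clone 47. A count of 0 allowed up to 0.06655 CPM (counts scaled to a common library size, with the TMM factors described below) in the control, 0.0742 in clone 41 and 0.0688 in clone 47, taken as 3 counts. Ratios of 2 libraries are given with exact conditional binomial 95% intervals. These intervals and floors cover counting error only, since PCR copies are not independent molecules.

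From the counts, genes were filtered with filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 10203 genes, and libraries were scaled by TMM. Knock-in was compared with control by edgeR's quasi-likelihood F test (estimateDisp, glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. The fit has 1 residual degree of freedom per gene, and the lone control is assumed to vary like the clones. The design fixed before the data were examined did not say which of edgeR's 2 quasi-likelihood estimators was meant. It listed the legacy estimator among the alternatives, so the newer one was set explicitly. By then a fit with the software default, the legacy one, had been seen: it gave 2 genes where the newer one gave 0, and both counts are printed wherever the 0 is. Standard errors of fitted log2 fold changes were derived from the F statistic.

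Sizes were counted on log2 CPM with a prior count of 2, as genes at least 2-fold from the control, without a test. Correlations of the fold changes of the 2 clones, which share 1 control library, were set beside 100 sets of simulated libraries with no effect. The 33 gene lists were written before the data were examined. Those with at least 5 tested members, 31 in number, were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over lists), and the others have values only. At the preset correlation camera compares a list's genes with the other tested genes. Its p-values then rest mainly on the spread over genes, which are taken as nearly independent. Each list's median per clone was placed among 10000 random lists of the same size matched on mean expression over 20 bins. Random lists do not keep the correlation among the genes of a list, so a median outside their range is no test by itself. List symbols were matched to the files directly or through older synonyms in the RefSeq gene table of assembly GRCg7b. The same table gave, for 95.4% of the tested genes, which genes neighbour each other; its coordinates were not used otherwise, since its assembly is not the authors' build.

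Genes were named by a rule also fixed in advance. It takes SRSF1 first and then a few further genes, among them UBN1 and the H3.3 genes; some items that the rule takes are not reported here. Next come up to 10 genes per direction past the threshold with a mean CPM of at least 5 and at least 2-fold in both clones. Where these are fewer, they are filled up to 10 by the larger of the smaller log2 fold of the 2 clones, and said not to have passed. It also takes up to 4 members per list and the 5 genes at each end of the clone 41 to clone 47 ratio. Genes known only by an identifier or as uncharacterised were skipped. UBN1 and H3.3 were put on a list because a publication title on SRSF1-3 names them, and it may rest on these libraries, so that list is not independent evidence.

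Alternatives were median-ratio, upper-quartile and total-count scaling, other filters on low counts, DESeq2 1.42.0, the legacy edgeR estimator, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), prior counts of 0.5 and 10, sizes of 1.5-fold and 4-fold, other list tests and each clone left out. Calculations used R 4.3.3, and plots used Python 3.11.15 with matplotlib 3.10.9. The scripts were tested on simulated counts over the 10203 genes: for knock-in against control, in 5 runs with 200 genes changed in each, 3.68% of genes changed 2-fold, 32.5% of those changed 4-fold and 82.7% of those changed 16-fold were recovered, with 29 false calls in all runs together. The GC content of transcripts was not analysed here.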

Results

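The series examined the transcriptome of chicken DT40-ASF B cells carrying an SRSF1-3 knock-in. It held 1 control library of untransfected cells and 2 knock-in libraries, clone 41 and clone 47. Total counts ranged from 41760372 in clone 47 to 44868987 in the control, and 10203 genes were tested. With 1 library per clone and 1 control, each value of a single library below has no replicate, and the intervals given are 95% intervals of counting error only. Clone 41 lay nearer to the control than to clone 47. The SD over genes of the log2 ratio was 0.63 for clone 41 against the control, 0.88 for clone 47 against the control and 1.00 for clone 41 against clone 47. The counts of clone 41 and clone 47 differed far beyond sampling noise, with a chi-square of 313 per degree of freedom.

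The level of SRSF1, the gene the knock-in concerns, was examined first. Its count was 1402 in the control, 1991 in clone 41 and 5645 in clone 47. It was at 1.58 times the control level in clone 41 (interval 1.48 to 1.70) and at 4.16 times in clone 47 (interval 3.92 to 4.42), so the clones differed by 2.63-fold. The fitted log2 fold change was 1.52 (SE 0.55), which did not pass edgeR's quasi-likelihood test (adjusted p = 1). Gene-level counts do not show which isoform these reads came from, nor whether reads of the human copy that this line is known to carry were counted or lost, so these values may not be the level of any 1 form of SRSF1.

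UBN1, a subunit of the HIRA complex that deposits histone H3.3, was at 0.949 times the control level in clone 41 (interval 0.892 to 1.01) and 1.08 times in clone 47 (interval 1.02 to 1.15). The H3.3 gene H3F3B was at 1.16 times in clone 41 and 1.83 times in clone 47. The related gene H3F3C was at 0.998 times in clone 41 (interval 0.983 to 1.01) and 3.66 times in clone 47 (interval 3.62 to 3.70), though reads of such near-identical copies may be divided unevenly. None of these genes passed the test, and no member of the list of genes from the publication title passed either over all genes or adjusted over the list alone. That list may have been chosen on these libraries.

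**Figure D1:**
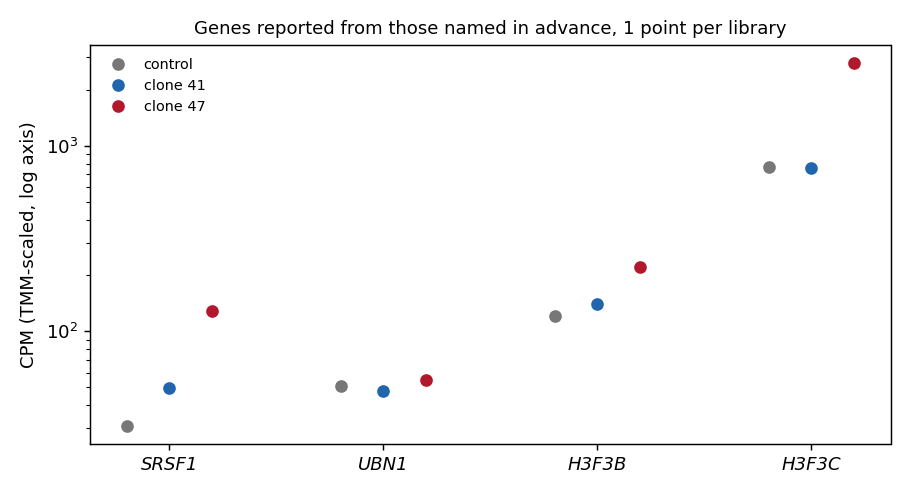
CPM (read counts scaled by TMM to a common library size, log axis) of 4 genes named in advance, with 1 point per library for the control, clone 41 and clone 47. SRSF1 stood at 1.58 times the control level in clone 41 and 4.16 times in clone 47, and H3F3C was at 0.998 times in clone 41 and 3.66 times in clone 47.

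Knock-in against control asked which genes differed between the 2 clones as a group and the control. The test did not require a difference in each clone. The control was 1 library of untransfected cells, while both knock-in libraries were transfected clones. Transfection, clonal history and the state of the control culture therefore differ along with the knock-in. These cannot be separated here, so a difference shared by the clones is not tied to the knock-in itself. No gene passed edgeR's quasi-likelihood test: 0 genes had an adjusted p below 0.05, and 81 had an unadjusted p below 0.05 where chance alone would give 510. The legacy estimator of the same test and DESeq2 each gave 2 genes, CDH8 (higher) and CFAP36 (lower), and limma-voom gave 1, CFAP36. CDH8, a cadherin, had 20 counts in the control, 638 in clone 41 and 847 in clone 47, or 35.6 times the control level in clone 41 (interval 22.8 to 58.6) and 43.8 times in clone 47 (interval 28.2 to 72.0). Its fitted log2 fold change was 5.30 (SE 1.04, edgeR adjusted p = 0.173; DESeq2 adjusted p = 1.92e-10). CFAP36 had 1238 counts in the control, 77 in clone 41 and 38 in clone 47, or 0.0693 times in clone 41 (interval 0.0543 to 0.0873) and 0.0317 times in clone 47 (interval 0.0223 to 0.0438), with a fitted log2 fold change of -4.31 (SE 0.76, edgeR adjusted p = 0.0749; DESeq2 adjusted p = 9.77e-06). The deposited FPKM of CFAP36 showed a far smaller difference, at 29.2 in the control, 18.8 in clone 41 and 20.9 in clone 47, and the fit on log2(FPKM + 1) gave -0.53 on that scale, so its size depended on which deposited measure was used. The FPKM of CDH8 was 0.0275, 1.31 and 1.67 in the same order.

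The other genes named by size in both clones did not pass the threshold. Higher than the control in both clones were CSTA, a cysteine protease inhibitor (3.22 times in clone 41 and 3.23 times in clone 47), TRH, the precursor of thyrotropin-releasing hormone (5.84 and 2.95 times), LIMCH1 (5.24 and 2.56 times), CCDC135 (3.13 and 2.77 times) and the calcium channel subunit gene CACNA2D3 (2.55 and 3.09 times). MDGA2, TYSND1, FAM38B and the transcription factor gene NFIB lay between 2.42 and 3.13 times in both clones. Lower in both clones were SPECC1 (0.388 and 0.212 times), ERO1L, an oxidoreductase of the endoplasmic reticulum (0.313 and 0.391 times), SCG5 (0.286 and 0.398 times), DSCAM (0.294 and 0.412 times), SLC7A4 (0.440 and 0.356 times), the proton channel gene HVCN1 (0.447 and 0.427 times), KCNF1 (0.457 and 0.207 times) and the Notch ligand gene JAG2 (0.447 and 0.481 times).

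By size alone, 893 genes were at least 2-fold from the control in clone 41 (327 higher, 566 lower) and 1733 in clone 47 (961 higher, 772 lower). In both clones and the same direction there were 290 genes (142 higher, 148 lower), where independent lists of those sizes would share 30.8 higher and 42.8 lower. Both comparisons share 1 control library, which cannot be split. Simulated libraries with no effect gave 810 such genes at the fitted dispersion and 13.0 with counting noise alone. The fitted dispersion comes from the 2 clones alone. It gave clone 41 a variance of log2 ratios of 0.808, where 0.398 was observed, so 810 overstates what noise would give. Neither simulation matched these libraries, so the overlap shows no shared effect by itself and the simulations do not exclude one. The same count with clone 41 in the place of the control was 512, and with clone 47 in its place 1245, so the count against the control was the smallest of the 3. It was 29 (17 higher, 12 lower) among the 7912 genes with a mean CPM of at least 5, where clone 41 alone had 138 and clone 47 alone had 668. Across genes, which are not independent replicates, the log2 folds of the clones correlated with a Pearson r of 0.161 and a Spearman rho of 0.0759. Their covariance was 0.0892. Simulated libraries without effect gave an r of 0.50 and a covariance of 0.403 at the fitted dispersion, and an r of 0.482 and a covariance of 0.0168 with counting noise alone. The same mismatch in spread limits this comparison.

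**Figure D2:**
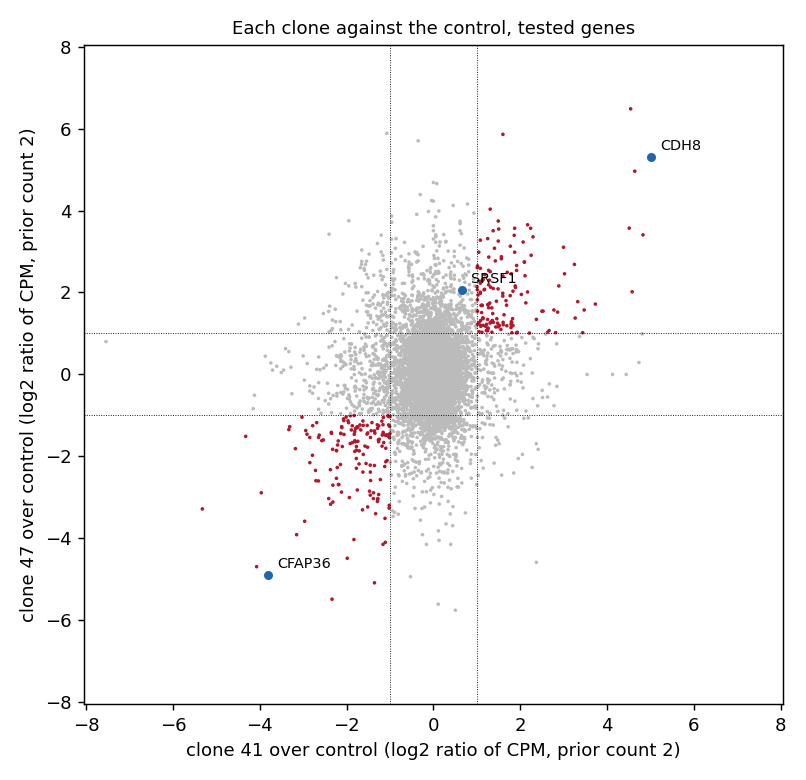
Log2 ratio of CPM (prior count 2) of clone 47 over the control against that of clone 41 over the control, with 1 point per tested gene; dotted lines mark 2-fold. The 290 genes at least 2-fold from the control in the same direction in both clones are red, the spread is wider along the axis of clone 47 (SD 0.88) than along that of clone 41 (SD 0.63), and CDH8 and CFAP36 lie far out in opposite corners.

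Gene groups fixed in advance were compared next. No list had a member past the threshold, over all genes or adjusted over the list alone. Camera called 1 of 31 tested lists, B cell identity and receptor signalling, lower in the knock-in clones (adjusted p = 0.00131). This call takes genes as nearly independent (preset correlation 0.01), so it does not show that the difference exceeds the spread between libraries. The correlation estimated for this list was 0.072, itself from 1 residual degree of freedom. With an estimated correlation camera gave this list an adjusted p = 0.974. That form of the test has 1 residual degree of freedom here and could hardly call any list, so it does not decide for or against the call. Of the 35 tested members of the B cell list, 17 were lower than the control in both clones and 4 were higher in both. Its median log2 ratio was -0.05 in clone 41, at percentile 12.9 of matched random lists, and -0.57 in clone 47, below each of 10000 random lists, so clone 47 carried most of the difference. At least 2-fold lower in clone 47 were 11 members. TNFRSF13B, a receptor for B cell survival factors, was at 0.574 times the control level in clone 41 and 0.436 times in clone 47, and BACH2, a transcription factor of B cells, was at 0.632 and 0.455 times. The kinase gene BLK had only 40, 9 and 11 counts in the control, clone 41 and clone 47, and TNFRSF13C had 22, 9 and 7.

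Plasma cell genes, 9 tested, were not called (adjusted p = 0.0683), with medians of -0.21 in clone 41 and -0.58 in clone 47. IRF4 was at 0.737 and 0.262 times the control level in clone 41 and clone 47, PRDM1 at 0.709 and 0.309 times, and JCHAIN, the immunoglobulin joining chain, at 0.685 and 0.440 times. Markers of other cell types were not called. CD28 of the T and NK cell list was at 0.223 and 0.129 times the control level, CD247 was at 0.522 and 0.457 times, and LCK had 12 counts in the control, 5 in clone 41 and 113 in clone 47. That list of 7 tested genes had an adjusted p of 0.262. Myeloid markers, also 7 tested, had a median of -0.52 in clone 41 and 0.62 in clone 47 (adjusted p = 0.774), with CEBPB at 1.03 and 2.03 times. No erythroid or thrombocyte marker was tested, and fibroblast and epithelial markers, 6 tested, had an adjusted p of 0.885.

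Of the splicing and RNA-processing groups, SR proteins lay outside the middle 95% of random lists in clone 47 and the 3 others did not. Several lists of other kinds lay outside it too, so this was not particular to SR proteins. Examples in clone 47 were cell cycle (percentile 99.8), oxidative phosphorylation (99.9) and heat shock (0.39). In clone 41 ribosomal proteins and glycolysis and hypoxia were both at percentile 100. SR proteins and their kinases, 19 tested, had a median of 0.02 in clone 41 and 0.47 in clone 47, at percentile 99.99 of 10000 random lists, and were not called (adjusted p = 0.121). Besides SRSF1, the SR protein kinase genes CLK1, CLK3 and CLK4 were at 1.16, 1.28 and 0.927 times the control level in clone 41 and at 2.15, 2.14 and 2.04 times in clone 47. Other members lay lower in clone 47, named after their values were seen: SRPK1 and SRPK2, also SR protein kinase genes, were at 0.586 and 0.596 times and SRSF3 and SRSF5 at 0.586 and 0.596 times. The list of hnRNPs and splicing regulators, 26 tested (adjusted p = 0.303), had medians of 0.03 in clone 41 and -0.06 in clone 47, although single members differed in clone 47: PTBP2 was at 0.908 and 3.69 times and HNRNPK at 0.820 and 2.60 times in clone 41 and clone 47. The spliceosome core list, 30 tested (adjusted p = 0.949), was at percentile 71.5 of random lists in clone 47, and its member SNRNP40 was at 1.05 and 2.36 times. The exon junction and nonsense-mediated decay list, 14 tested (adjusted p = 0.365), was at percentile 63.0 in clone 47, with RNPS1 at 0.957 and 2.56 times and GADD45A at 0.888 and 2.79 times. None of these lists was called.

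DNA and chromatin groups were not called. Genes of recombination and gene conversion, 21 tested (adjusted p = 0.303), had medians of 0.03 and -0.33; RAD54B was at 0.892 and 0.461 times the control level in clone 41 and clone 47 (FPKM 8.01 in the control, 6.28 in clone 41 and 2.34 in clone 47). Adjusted p values were 0.949 for end joining, 0.949 for H3.3 histones and chaperones and 0.885 for chromatin organisers and modifiers. In the last list SATB1 was at 1.14 and 2.68 times. Replication-dependent histones, 11 tested (adjusted p = 0.609), had medians of 0.18 and -0.54, with HIST1H3H at 0.990 and 0.310 times. Cell cycle genes, 37 tested (adjusted p = 0.774), had medians of -0.03 and 0.23, with PLK1 at 0.884 and 0.494 times and E2F1 at 0.933 and 1.91 times.

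Among stress and metabolic groups, heat shock genes, 16 tested (adjusted p = 0.262), had medians of -0.03 in clone 41 and -0.47 in clone 47. HSPA8 was at 0.568 and 0.579 times the control level and HSP90AA1 at 0.809 and 0.428 times, while BAG3 had 3 counts in the control, 12 in clone 41 and 284 in clone 47. Oxidative phosphorylation genes, 39 tested, had medians of 0.11 and 0.23 (adjusted p = 0.059), 23 were higher in both clones and 0 were lower in both, and UQCRFS1 was at 1.28 and 1.78 times. Genes of the mitochondrial genome, 13 tested, had medians of 0.39 and 0.27 (adjusted p = 0.0821), and 12 were higher in both clones, such as CYTB at 1.60 and 1.14 times. Mitochondrial genes held 3.33% of counts in the control, 4.05% in clone 41 and 4.42% in clone 47. With total-count scaling in place of TMM, camera called 4 lists at the preset correlation (B cell identity and plasma cell lower, oxidative phosphorylation and mitochondrial genome higher), and on log2(FPKM + 1) it called 3 (B cell identity and T and NK cell markers lower, mitochondrial genome higher). None of these calls held with an estimated correlation, a setting chosen after seeing the data (adjusted p = 0.979 for each of the 4 and adjusted p = 0.957 for each of the 3 with an estimated correlation). That setting has 1 residual degree of freedom here and could hardly call any list, so it decides nothing about these calls. Ribosomal protein genes, 64 tested (adjusted p = 0.287), had medians of 0.32 in clone 41 and -0.11 in clone 47, with RPL15 at 1.62 and 1.73 times. Glycolysis and hypoxia genes, 26 tested (adjusted p = 0.303), had medians of 0.30 and 0.03, with LDHA at 0.833 and 0.396 times and LDHB at 1.46 and 1.63 times. Interferon response genes, 17 tested (adjusted p = 0.949), went both ways in clone 47, 5 at least 2-fold higher and 3 at least 2-fold lower; IFITM5 was at 0.738 and 8.11 times by counts (FPKM 1.89 in the control, 1.61 and 8.56) and DTX3L at 0.498 and 5.21 times. For the NF-kB target list, 12 tested, the adjusted p was also 0.949, and CD83 was at 0.352 times in clone 41 and 7.71 times in clone 47. The remaining lists, which were apoptosis regulators, unfolded protein response and ER, immediate early, MHC and antigen presentation, cholesterol synthesis, MYC and nucleolar, cell adhesion and cytoskeleton and transcription elongation and topoisomerases, had adjusted p values between 0.262 and 0.949. In the adhesion list ACTN1 was at 0.727 and 0.171 times. The median and the mean of the fitted log2 fold changes differed in sign for 8 lists that were not called. These were heat shock (-0.30 and 0.12), NF-kB targets (-0.02 and 0.20), interferon response (-0.02 and 0.37), cell adhesion and cytoskeleton (-0.13 and 0.03), spliceosome core (-0.05 and 0.04), H3.3 histones and chaperones (-0.01 and 0.04), and chromatin organisers and modifiers and apoptosis regulators, with means within 0.01 of 0. Both were above 0 while camera pointed lower for MHC and antigen presentation and for unfolded protein response and ER. Total-count scaling moved the median of all genes to -0.08 in clone 41 and 0.06 in clone 47, enough to turn the sign of list medians nearer to 0 than that.

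**Figure D3:**
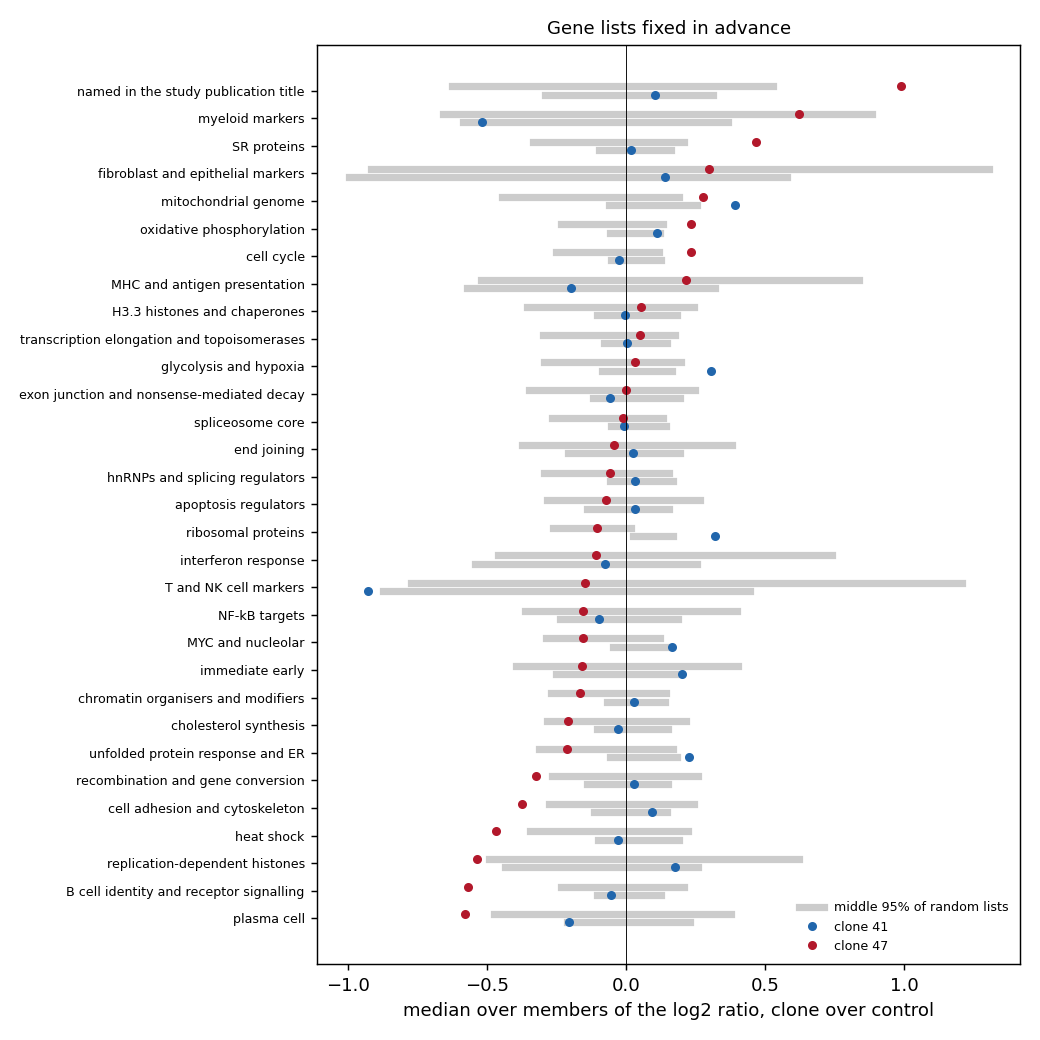
Median over members of the log2 ratio of each clone over the control for gene lists fixed in advance (points), with the middle 95% of 10000 random lists of the same size matched on mean expression (grey bars). B cell identity and receptor signalling was at -0.57 and SR proteins at 0.47 in clone 47, and ribosomal proteins at 0.32 in clone 41.

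Clone 41 against clone 47 compared the 2 knock-in libraries directly. At least 2-fold apart were 2125 genes, 885 higher in clone 41 and 1240 higher in clone 47. No test was possible with 1 library per clone. The largest ratios among genes with a mean CPM of at least 5 included K123, which had 10195 counts in the control, 47 in clone 41 and 17193 in clone 47. The desmosome gene DSP was at 0.249 times the control level in clone 41 and 13.6 times in clone 47, DRP2 at 0.307 and 8.33 times, CD83 at 0.352 and 7.71 times and the prostaglandin receptor gene PTGER3 at 0.309 and 6.49 times. Higher in clone 41, FABP5, a fatty acid binding protein gene, had 711 counts against 8 in clone 47 (557 in the control), ARHGAP8 was at 3.00 times the control level in clone 41 and 0.172 times in clone 47, GTF2A1L was at 1.22 and 0.0746 times, the Toll-like receptor gene TLR4 at 2.05 and 0.179 times and P2RY10 at 1.10 and 0.107 times. Total-count scaling gave a median log2 ratio of -0.16 for clone 41 over clone 47, against -0.03 with TMM. The split by direction depended on processing: 707 genes were higher in clone 41 and 1502 in clone 47 with total-count scaling, 801 and 1342 with upper-quartile scaling, and 896 and 983 with the trend on transcript length and expression removed, a setting chosen after seeing the data.

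Genes that neighbour each other on the chromosomes of the GRCg7b annotation had similar log2 ratios, a pattern looked for after the values were seen. The SD of the medians of 172 runs of 40 neighbouring genes was 0.17 for clone 41 over the control, against at most 0.06 in 100 shuffles of the genes, and 0.16 for clone 47, against at most 0.11. The 556 genes of the chromosome that carries RPS3A and RPL9 had a median of -0.37 in clone 41 and -0.15 in clone 47, and the 203 genes of the one that carries RPL13 and AARS had 0.37 and 0.19. CDH8 lay on the latter.

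**Figure D4:**
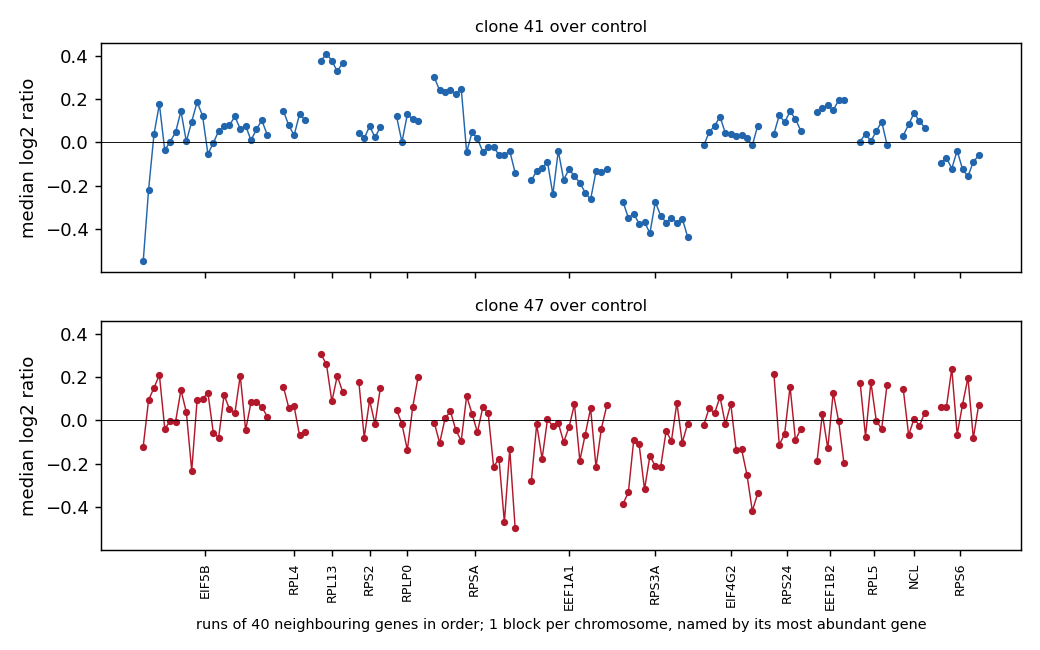
Median log2 ratio over the control of each run of 40 neighbouring genes (points), in order along each of the larger chromosomes (blocks, named by the most abundant gene), for clone 41 (upper panel) and clone 47 (lower panel). The chromosome of RPS3A lies near -0.37 and that of RPL13 near 0.37 in clone 41, with steps within some chromosomes.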

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

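Of the tests in this part, the one of other scalings was written before its result was seen, and the tests of a length or expression trend and of other cells were chosen after. There were 141 genes at least 2-fold from the control in opposite directions in the 2 clones, which drew attention because the clones share 1 genotype label. Independent lists would give 78.1 and simulated libraries with no effect 77.1 at the fitted dispersion. In that simulation clone 41 varied more around the control than was observed (variance of log2 ratios 0.808 against 0.398), so 77.1 is an inexact yardstick. Of the 141 genes, 110 were lower in clone 41 and higher in clone 47, such as DSP, and the difference was not tested. Among the 7912 genes with a mean CPM of at least 5, only 20 went in opposite directions, so most of the 141 were genes with few counts. The comparisons on counts did not use the 383 genes listed in the FPKM table alone. Of these, 1 was at least 2-fold above the control in both clones. The microRNA gene gga-mir-6542 had an FPKM of 0.641 in the control, 99.2 in clone 41 and 113 in clone 47. Another 6 small RNA genes of that table went the other way and were listed at 0 in both clones, among them MIR762 (FPKM 4621 in the control) and MIR1808 (742). All of these, gga-mir-6542 included, were among the 12 genes past the threshold with limma-trend on log2(FPKM + 1) over genes with FPKM of at least 1 in at least 1 library. The libraries were enriched for mRNA, and these genes have no deposited counts to check the FPKM against. Such values may therefore not measure the level of small RNAs.

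Clone 47 lay farther from the control than clone 41, with 1733 against 893 genes at least 2-fold away, a ratio of 1.94. The edgeR quasi-likelihood test with each library in turn set apart from the other 2 gave 0 genes for the control (81 at an unadjusted p below 0.05; 2 genes by DESeq2 and the legacy estimator, 1 by limma-voom), 1 gene for clone 41 and 1216 for clone 47. The 3 splits are too few for a share under 0.05. With clone 47 set apart, the spread comes from the control and clone 41 alone, the closest of the 3 pairs (SD 0.63), so the high count restates this structure of the samples and adds no evidence. Likewise, the 0 for the control rests on the spread between the clones, the most distant pair (SD 1.00). Scaling set by a few abundant genes would bring the ratio of the 2 counts down to at most 1.5, but the lowest ratio under 3 other scalings was 1.88, and after a trend on effective transcript length and mean expression was removed the ratio was 2.04. Cells of another type mixed into the clone 47 culture would lower every B cell gene alike. Of 32 members of the B cell list with a mean CPM of at least 5, 5 (EBF1, BCL10, CD40, BCL6 and CD72, named after their values were seen) had counting intervals wholly above the control level and 24 wholly below. These 2 libraries differ far beyond counting noise (chi-square 262 per degree of freedom), so such intervals decide nothing and this explanation stays open. SRSF1 level, clonal history and culture differ together between these 2 libraries, so no biological explanation was tested.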

How the results depend on the processing

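Settings that centre each chromosome, remove the trend on transcript length and expression, combine the mean CPM filter with a left-out clone, or estimate the correlation without TMM or on FPKM were chosen after seeing the data, and the others before; the cause of each move below was not tested, except that stricter filters leave fewer genes and larger prior counts or pseudocounts shrink low genes. The edgeR count of genes past the threshold, 0 (81 at an unadjusted p below 0.05), was also 0 under 3 other scalings, without the low-count filter and with limma-trend on either FPKM pseudocount. It was 2 with a mean CPM of at least 5, 2 with DESeq2, 2 with the legacy estimator, 1 with limma-voom, and 12 with limma-trend on log2(FPKM + 1) over genes with FPKM of at least 1 in at least 1 library. Those 12 were TMSB10 and small RNAs such as MIR762, Y_RNA and gga-mir-6542, and neither CDH8 nor CFAP36 was among them. The count of genes at least 2-fold from the control in both clones, 290, lay between 251 and 390 under the 3 scalings, no filter, a prior count of 0.5, chromosome centring and trend removal. It was 29 with a mean CPM of at least 5, 153 with a prior count of 10, 22 on log2(FPKM + 1), 116 on log2(FPKM + 0.1), 678 at 1.5-fold and 41 at 4-fold. With 1 clone left out it ranged from 893 (clone 41 alone) to 1733 (clone 47 alone), and with a mean CPM of at least 5 from 138 to 668, because only 1 clone then has to qualify. The count of genes at least 2-fold apart between the clones, 2125, was 938 with a mean CPM of at least 5 and 804 on log2(FPKM + 1), and within 1.5 times otherwise. Camera's 1 called list became 0 with an estimated correlation, 0 with fry, 4 without TMM and 3 on log2(FPKM + 1), and 0 in both of these with an estimated correlation. An estimated correlation and fry both rest on 1 residual degree of freedom here, so their counts of 0 do not decide whether a list moved. The r of 0.161 between the clones was 0.134 with a prior count of 10, 0.0513 with a mean CPM of at least 5 and 0.110 on log2(FPKM + 1). Of 35 named genes, UBN1 (-0.027) and TLR4 (-0.31) took the opposite sign with limma-trend on log2(FPKM + 1), and CDH8 and CFAP36 passed with DESeq2. With 1 clone left out there are no residual degrees of freedom, so no gene or list could be tested; the B cell list's median of -0.29 ranged from -0.57 (clone 47 alone) to -0.05 (clone 41 alone). No paired analysis was possible because the control group has 1 library. Depth limits genes with few counts, such as BLK.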

Other observations

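Both tests in this part were chosen after the pattern was seen. Within the B cell list, PTPRC, the CD45 phosphatase of leukocytes, was at 1.28 times the control level in clone 41 and 0.253 times in clone 47, and the B cell signalling genes BTK (0.752 and 0.420 times) and BLNK (1.05 and 0.470 times) were also lower in clone 47. PAX5, the B-lineage transcription factor, was at 1.03 and 1.05 times. These genes were picked after their values were seen and none passed the test.

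Neighbouring genes shifted together in each clone. On the most shifted chromosome in clone 41, which carries RPS3A and RPL9, 13 of 13 runs of 40 genes had a median below 0, and less expressed and more expressed genes had medians of -0.40 and -0.33. After the trend on transcript length and mean expression was removed, the median of that chromosome was still -0.36, which argues against such a trend as the whole cause. A candidate explanation is DNA copy number that differs between the libraries, since 92.1% of the genes on that chromosome were below the control level in clone 41 and their median was 0.775 times that level. This is a hypothesis, as DNA was not analysed here. In clone 47 the same chromosome had 12 of 13 runs below 0 and 61.7% of its genes below the control level, with a median of -0.15. The chromosome that carries ENO1 and YBX1 had a median of -0.48 in clone 47 and 0.07 in clone 41, so that shift was in clone 47 and not in clone 41. Whether the control or a clone carries each difference stays open where both clones moved. This holds for the chromosome of RPL13 and AARS and for that of RPS3A and RPL9. GC content was not tested.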
